A study of Mus musculus with 6 samples.

How the data were processed

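Total RNA from the cortex of wild type mice and of littermates lacking HtrA2, a serine protease of the mitochondrial intermembrane space, was measured at postnatal day 29 on an Affymetrix expression array. The labels give 6 samples, 3 wild type and 3 knockout, with 1 array each. Biotin-labelled RNA was hybridised, per the labels' protocols. The deposited table holds 45101 probe sets per array.

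The deposited values were read as log2 values. RMA, which corrects background, quantile normalizes the arrays and summarizes each probe set, is named in the submitters' processing notes, without a version. The base of the logarithm is not given in the sources used here and was taken as 2 from the range of the values. Array medians lay between 6.40 and 6.45. RMA forces the arrays onto nearly the same distribution, so a change shared by most genes would not appear, and it compresses differences among dim probe sets. The arrays give no counts, so their number, 3 per group, limits the precision.

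From the deposited values, 64 array control probe sets were left out and 45037 were tested, with no filter on brightness. The platform annotation gave 34945 of these 1 gene symbol, 932 several and 9160 none. Of the probe sets with 1 symbol, 34741 were matched by gene identifier to the RefSeq gene table of assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. No gene was named from a probe set with several symbols. The named probe sets covered 18193 genes. A gene counted as changed if at least 1 probe set that names it alone passed.

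Knockout was compared with wild type by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over all tested probe sets, at an adjusted p under 0.05. Log2 fold changes are knockout minus wild type. Gene lists were tested with limma's camera on 1 probe set per gene, the one with the highest mean over all arrays, with a preset correlation of 0.01 and adjustment over 33 lists. The 34 lists hold 17 pathway or response lists, 16 cell type lists and 1 sex-linked list kept as a check, and 578 of their 629 entries were measured. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to be later. Named genes were Htra2, the 12 largest rises and the 12 largest falls among called probe sets whose groups do not overlap, up to 4 members of each list by smallest p (2 where none passed), and called genes near Htra2. Genes near Htra2 were compared with all others by Fisher's exact test.

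The labels say that the mice were littermates of each other but do not state that each array came from a separate animal, so the p-values measure the spread between these samples. They give no batch, litter or scan date. The replicate numbers of the groups are not said to pair animals, so they were used as a block only in an alternative. Other alternatives were a filter on dim probe sets, limma-trend with robust moderation, further quantile normalization, median centring, array weights, the Y-linked level as a covariate, other thresholds, 1 probe set per gene, other list tests, other neighbourhood sizes and leaving out each array. Leaving out both replicates numbered 2 was added after the values were seen.

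The fit was tested on simulated data of 3 arrays against 3 over 45037 probe sets. It recovered 78 of 100 probe sets changed by 1 log2 unit and 100 of 100 changed by 2, with 4 false calls among 182. In a simulation over 18193 genes and 33 lists, the list shifted by -0.4 was called and no other, and with no shift 0 lists were called. Simulated genes vary independently, which genes in tissue do not.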

Results

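The series asks which transcripts differ in the cortex of mice without HtrA2, in a region that the submitters describe as free of neuron loss. There were 3 wild type and 3 knockout arrays of cortex from littermates at postnatal day 29. Values are RMA levels on the log2 scale, ± gives the standard error of a log2 fold change unless it is called SD, and n = 3 in each group throughout. Tests are limma's moderated test with Benjamini-Hochberg adjustment over all 45037 probe sets.

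The knocked-out gene itself, Htra2, was measured by 2 probe sets, which moved in opposite directions. The first fell by 2.27 ± 0.17 on the log2 scale, from 8.92 ± 0.0833 (SD) in wild type to 6.65 ± 0.374 (SD) in the knockout (adjusted p = 0.00227). The level was 6.42 and 6.45 in knockout replicates 1 and 3 and 7.08 in replicate 2, below every wild type array. The second rose by 1.11 ± 0.08, from 8.21 ± 0.0833 (SD) to 9.33 ± 0.0444 (SD) (adjusted p = 0.00169). Where their probes lie relative to the deleted part is not given in the sources used here, so the rising probe set checks no label.

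Knockout cortex had 796 changed probe sets, 398 higher and 398 lower, which name 601 genes. Of these genes 298 were higher and 304 lower, and Htra2 is counted in both. The groups did not overlap at 23.2% of all probe sets, where 10% is expected by chance for 3 against 3. Changes over 2-fold were found at 82 called probe sets, 53 higher and 29 lower. The count rests on few arrays: without wild type replicates 1, 2 and 3 it was 70, 65 and 107. Without knockout replicate 2, the array farthest from its group, it was 3037. Counts of list members without wild type replicate 2, given below, are to be read against this general loss of calls.

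The largest rises were led by Slc7a3, a cationic amino acid transporter, which rose by 2.25 ± 0.12 (4.76-fold, adjusted p = 0.000452), and Cyb5r1, a cytochrome b5 reductase, which rose by 2.15 ± 0.08 (4.44-fold, adjusted p = 7.63e-05). Ddit3, which encodes the stress transcription factor CHOP, rose by 1.86 ± 0.07 at 1 of its 2 probe sets, while the other differed by -0.01. Shmt2, the mitochondrial serine hydroxymethyltransferase, rose by 1.60 ± 0.08. Gm38403 rose by 2.08 ± 0.13, Etnppl, a phospholyase abundant in astrocytes, by 1.77 ± 0.23, and Itih3 by 1.52 ± 0.14. The interferon-induced genes Ifit3 and Usp18 rose by 1.51 ± 0.21 and 1.45 ± 0.27. 9330179D12Rik, 1810010H24Rik and Spaca6 rose by 1.47 ± 0.16, 1.45 ± 0.22 and 1.45 ± 0.12, Spaca6 at 1 of its 3 probe sets, another of which differed by 0.12.

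Homer1, a scaffold protein of the synapse, had the largest fall after Htra2 and fell by 2.27 ± 0.17 (4.83-fold lower, adjusted p = 0.00249), and 3 of its 6 probe sets fell. Arc, induced by synaptic activity, fell by 1.71 ± 0.33 with an adjusted p of 0.0482, close to the threshold. Ptgs2, which encodes cyclooxygenase-2, fell by 1.42 ± 0.19, and Nptx2, a pentraxin of excitatory synapses, by 1.24 ± 0.11. Dio2, the deiodinase that activates thyroid hormone, fell by 1.27 ± 0.09, and Msmo1, a sterol oxidase of cholesterol synthesis, by 1.25 ± 0.10 at 1 of its 2 probe sets, while the other differed by 0.03. Dmkn fell by 1.47 ± 0.13, Kcnv1, a potassium channel subunit, by 1.21 ± 0.11 and at all 3 of its probe sets, Acvr1c by 1.19 ± 0.08 at 1 of its 3 probe sets, another of which differed by -0.08, and Dusp6, a phosphatase of the ERK pathway, by 1.15 ± 0.17. Ighm, the immunoglobulin mu heavy chain, fell by 1.41 ± 0.14, with 3 of its 11 probe sets past the test and only 4 lower. Gigyf2 fell by 1.29 ± 0.15 at the probe set with the largest change, and 2 of its 4 probe sets fell, while another differed by 0.11.

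All named genes past the test kept their direction when 1 array was left out, but this was fixed in advance, since their groups did not overlap. Not all kept their call. Of 72 named probe sets past the test, Htra2 aside, 24 kept it in all 6 omissions, among them Slc7a3, Cyb5r1, Ddit3, Shmt2, Homer1, Nptx2 and Msmo1. Another 24 kept it only without knockout replicate 2: Usp18, 1810010H24Rik, Arc, Slc1a4, Hsph1, Bbc3, Ldha, Xaf1, Irf7, Rtp4, Nefm, Tac2, Syndig1l, Acsbg1, Aqp4, Gfap, Fbln5, Ugt8a, Tmem119, P2ry12, Alas2, Kcmf1, Mrpl35 and Egr4. The other 24, such as Ifit3 and Ptgs2, kept it in 2 to 5 omissions. With the Y-linked level as a covariate, 16 of the 72 lost their call: Usp18, Slc1a4, Hsph1, Ldha, Irf7, Neurod6, Tac2, Syndig1l, S100b, Olig2, Itgam, Tmem119, P2ry12, Alas2, Kcmf1 and Mrpl35. Median centring ended 3 of the calls (Syndig1l, Kcmf1 and Mrpl35), and leaving out both replicates numbered 2 ended 28, among them Arc, Ptgs2, Dusp6, Gfap and Aqp4.

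**Figure D1:**
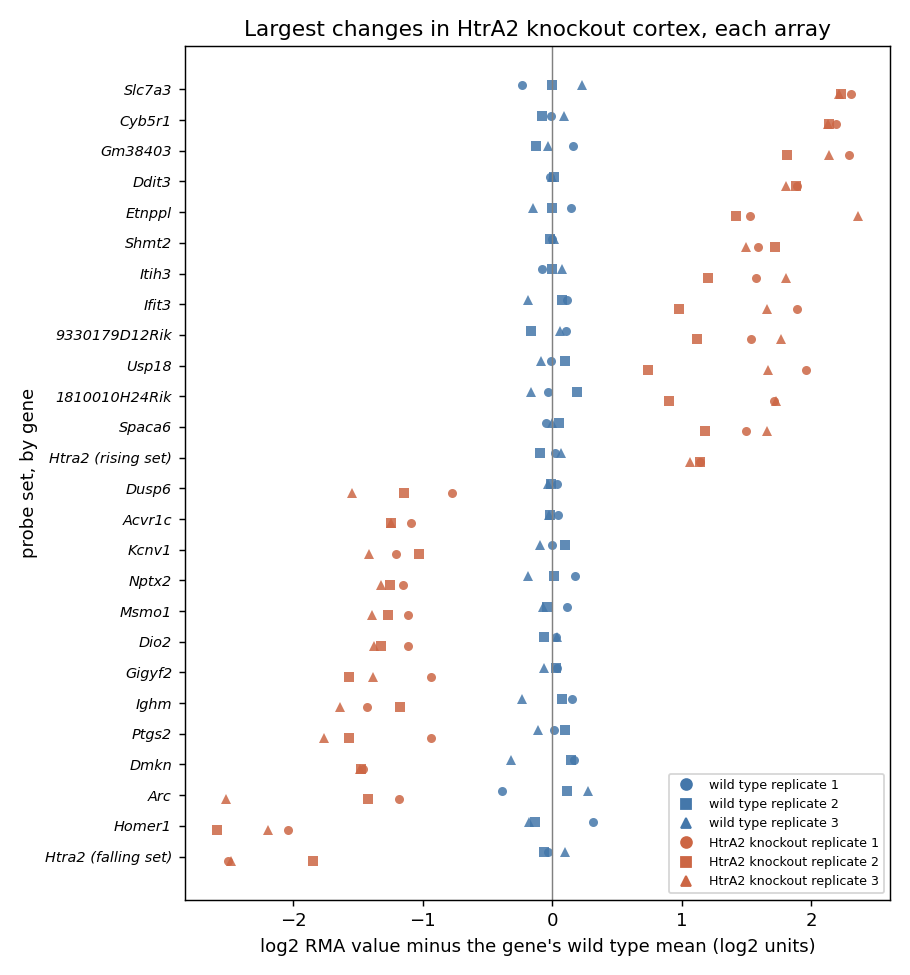
Each point is 1 array's log2 RMA value minus the wild type mean of that probe set (horizontal axis, log2 units), for both Htra2 probe sets and the 12 largest rises and falls (vertical axis). Colours mark the genotype and shapes the replicate, and no gene shown has overlapping groups. Knockout replicate 2 lies nearer to wild type at Ifit3 and Usp18 than the other knockout arrays, and not at Ddit3 or Homer1.

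Targets of the stress transcription factors ATF4 and CHOP had the most rising members of any list. Of 33 measured members 14 rose, 0 fell and 19 did not pass the test, and adjusted over the list alone 20 rose and 1 fell. Besides Ddit3 and Slc7a3, Chac1, a glutathione-degrading enzyme, rose by 1.20 ± 0.11 and Asns, asparagine synthetase, by 0.75 ± 0.07. The list stood higher by camera (median log2 fold change 0.39, adjusted p = 2.66e-11), with adjusted p = 0.0982 with an estimated correlation. Without wild type replicate 2, 3 members rose, and without knockout replicate 2, 16 did.

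Enzymes of serine, one-carbon and proline synthesis moved with them: 5 of 16 measured members rose and 0 fell, and adjusted over the list alone 8 rose. Next to Shmt2, Psph, which makes serine, rose by 0.81 ± 0.07, Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, by 0.74 ± 0.08 and the neutral amino acid transporter Slc1a4 by 0.58 ± 0.09. The median was 0.24 (camera adjusted p = 7.00e-07; adjusted p = 0.0946 with an estimated correlation). Without wild type replicate 2, 2 members rose.

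Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose at 10 of 20 measured members, with 0 falls, and at 14 adjusted over the list alone. The list also holds Xpot, which exports tRNA. Sars rose by 0.90 ± 0.08, Cars by 0.95 ± 0.09, Aars by 0.74 ± 0.07 and Mars1 by 0.72 ± 0.07. The median was 0.44 (camera adjusted p = 2.32e-13; adjusted p = 0.0982 with an estimated correlation). Without wild type replicate 2, 3 members rose, and without knockout replicate 2, 14 did.

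Mitochondrial chaperones and proteases shifted little. Of 21 measured members 1 rose, Hspa9, the mitochondrial Hsp70, by 0.51 ± 0.07, and it was also the 1 member that rose adjusted over the list alone. Clpp, Dnaja3 and Lonp1 differed by 0.28 ± 0.07, 0.25 ± 0.07 and 0.22 ± 0.07 without passing. The list's median was 0.08 (camera adjusted p = 0.0207; adjusted p = 0.329 with an estimated correlation), and its call was lost without knockout replicate 1. Endoplasmic reticulum chaperones were not called as a list (median -0.06, camera adjusted p = 0.130). There Herpud1 rose by 0.92 ± 0.07, the 1 of 20 members past the test on either adjustment, the other being adjusted over the list alone, while Calr, Hsp90b1 and Pdia4 differed by -0.29 ± 0.08, -0.27 ± 0.11 and -0.17 ± 0.07.

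Cytosolic heat shock proteins were lower, with 2 of 15 measured members past the test and 7 adjusted over the list alone. Hspa1b, an inducible Hsp70, fell by 0.88 ± 0.14 and Hsph1 by 0.51 ± 0.08, and Hspa4 and Cryab differed by -0.28 ± 0.08 and -0.35 ± 0.10. The median was -0.17 (camera adjusted p = 2.96e-05; adjusted p = 0.124 with an estimated correlation).

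Transcripts of nuclear-encoded subunits of the respiratory chain changed little, and the lists held no transcript encoded in mitochondrial DNA. No member of complex I passed among 34 measured at the probe set used in the list, though 2 fell at another probe set and 3 rose and 1 fell without knockout replicate 2, with 1 lower adjusted over the list alone, and the list was not called (median 0.03, camera adjusted p = 0.736). Ndufa1 differed by -0.36 ± 0.07 and Ndufa6 by 0.30 ± 0.07. Complexes II to V had 0 of 36 members past the test at the probe set used in the list, also adjusted over the list alone, and 1 fell at another probe set. Their list was lower with a median of -0.05 (camera adjusted p = 0.0178; adjusted p = 0.291 with an estimated correlation), a call lost without wild type replicate 1. Cycs, cytochrome c, differed by -0.29 ± 0.08 and Cox6b1 by -0.20 ± 0.07. Mitochondrial biogenesis genes were not called (median 0.06, mean -0.004, camera adjusted p = 0.978), with 0 of 18 members past the test, also adjusted over the list alone. Polg differed by -0.38 ± 0.12 and Fis1 by 0.21 ± 0.07.

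Genes of cholesterol synthesis fell together: 9 of 17 measured members fell and 0 rose, and adjusted over the list alone 15 fell. Besides Msmo1, Cyp51 fell by 0.92 ± 0.08, Idi1 by 1.0 ± 0.09 and Nsdhl by 0.72 ± 0.07. The median was -0.61 (camera adjusted p = 6.04e-17; adjusted p = 0.0946 with an estimated correlation). Without wild type replicate 2, 3 members fell, and without knockout replicate 2, 12 did. In hypoxia and glycolysis genes, Ldha, lactate dehydrogenase A, fell by 0.46 ± 0.08 as 1 of 21 members, and 3 fell adjusted over the list alone. Pfkl, Pfkp and Egln3 differed by -0.42 ± 0.09, -0.27 ± 0.07 and -0.29 ± 0.11, and the list's median was -0.11 (camera adjusted p = 0.00464; adjusted p = 0.228 with an estimated correlation).

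Immediate early genes, which neurons switch on with activity, were lower at every measured member. Of 21 members 6 fell and 15 did not pass, and adjusted over the list alone 15 fell. Besides Arc, Nptx2 and Ptgs2, Nr4a1 fell by 1.0 ± 0.10, the growth factor Bdnf by 0.81 ± 0.09 and Egr4 by 0.64 ± 0.12. The probe set of Homer1 with the highest mean, used in the list, did not pass. The median was -0.64 (camera adjusted p = 1.02e-12; adjusted p = 0.133 with an estimated correlation). Without wild type replicate 2, 2 members fell, and without knockout replicate 2, 10 did.

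Interferon response genes rose at 7 of 16 measured members, with 0 falls, and at 12 adjusted over the list alone. Next to Ifit3 and Usp18, Xaf1 rose by 0.92 ± 0.13, the transcription factor Irf7 by 0.52 ± 0.08 and Rtp4 by 1.25 ± 0.20. The median was 0.65 (camera adjusted p = 1.26e-09; adjusted p = 0.284 with an estimated correlation). The list's mean deviation from wild type was 0.96 and 0.90 in knockout replicates 1 and 3 and 0.40 in replicate 2. Replicate 2 was also the knockout array nearest to wild type in the meningeal list (0.07). In that array the interferon list still lay above every wild type array (-0.07 to 0.07). Its meningeal value lay within the wild type range (-0.07 to 0.13). This rests on 1 array, so the interferon rise is not fully separated from a difference in meningeal tissue. Without wild type replicate 2, 0 members passed the limma test, and without knockout replicate 2, 13 rose. The shift of the list was not smaller without wild type replicate 2 (median 0.67, camera adjusted p = 2.81e-10).

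Among the other response lists, none was called. Of apoptosis and p53 genes, Bbc3, which encodes the cell death activator PUMA, rose by 0.63 ± 0.10 as the 1 of 25 members past the test, the same number as adjusted over the list alone; the count was 0 without wild type replicate 2, and 4 rose and 1 fell without knockout replicate 2. Bcl2l11, Bid and Bcl2 differed by 0.45 ± 0.11, 0.46 ± 0.13 and -0.22 ± 0.08 (list camera adjusted p = 0.388). That list's mean deviation was 0.14 and 0.22 in knockout replicates 1 and 3 and -0.07 in replicate 2, and without replicate 2 the list was called (camera adjusted p = 0.0258). The antioxidant and glucocorticoid lists below were also called without that array (camera adjusted p = 0.0451 and 0.0158). Antioxidant genes had 0 of 19 members past the test, also adjusted over the list alone, with Hmox1 at 0.39 ± 0.10 and Gclm at 0.42 ± 0.13 (list camera adjusted p = 0.165). Glucocorticoid targets had 0 of 14, also adjusted over the list alone, with Fkbp5 at 0.59 ± 0.16 and Zbtb16 at 0.32 ± 0.13 (list camera adjusted p = 0.0861), and a mean deviation of 0.54 in knockout replicate 3 against 0.13 and -0.0007 in replicates 1 and 2. Parkinson disease genes had 0 of 11 members past the test at the probe set used and 1 lower adjusted over the list alone, with Lrrk2 at -0.52 ± 0.12 and Gigyf2 at -0.27 ± 0.09 (list camera adjusted p = 0.0516). That list was called as lower without wild type replicate 2 or knockout replicate 1 (camera adjusted p = 0.0402 and 0.0306), and in other settings.

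Astrocyte lists moved in opposite directions. Of 16 genes of the general astrocyte list 3 fell, the water channel Aqp4 by 0.59 ± 0.09, S100b by 0.58 ± 0.10 and Acsbg1 by 0.49 ± 0.08. Adjusted over the list alone 6 fell and 1 rose. Ntsr2 differed by -0.28 ± 0.08, and the median was -0.17 (camera adjusted p = 0.00339; adjusted p = 0.291 with an estimated correlation). The mean deviation was -0.16 and -0.22 in knockout replicates 1 and 2 and -0.03 in replicate 3, near the wild type arrays. The count was 0 without wild type replicate 2, and without knockout replicate 2 it was 4 while the median shrank to -0.09. Of 14 genes of reactive astrocytes 2 rose, the intermediate filament Gfap by 0.63 ± 0.09 and Fbln5 by 0.84 ± 0.13, and adjusted over the list alone 5 rose. Cxcl10 differed by 2.28 ± 0.51 and Timp1 by 0.52 ± 0.16 without passing. The median was 0.32 (camera adjusted p = 0.00235; adjusted p = 0.124 with an estimated correlation), and the mean deviation was 0.52 and 0.51 in knockout replicates 1 and 3 and 0.29 in replicate 2. The count was 0 without wild type replicate 2 and 6 without knockout replicate 2. The meningeal list was also nearest to wild type in knockout replicate 2 (0.07), within the wild type range of -0.07 to 0.13. The reactive list, at 0.29 in that array, still lay above every wild type array (-0.05 to 0.04). This rests on 1 array, so the rise is not fully separated from a difference in meningeal tissue.

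Microglial lists also parted. Of 17 genes of the general microglia list 3 fell, Itgam by 0.72 ± 0.12, P2ry12 by 0.60 ± 0.11 and Tmem119 by 0.47 ± 0.08. Adjusted over the list alone 7 fell. Selplg differed by -0.47 ± 0.12, and the median was -0.22 (camera adjusted p = 0.000118; adjusted p = 0.291 with an estimated correlation). Leaving out wild type replicate 2 left 0 members past the test, and leaving out knockout replicate 2 left 5. Of 17 genes of activated microglia 1 rose, the class I antigen-presenting gene H2-D1, by 0.72 ± 0.10, and adjusted over the list alone 2 rose. Cd74, Clec7a and Ccl3 differed by 0.58 ± 0.12, 0.41 ± 0.13 and 0.54 ± 0.18, and the median was 0.16 (camera adjusted p = 0.00672; adjusted p = 0.133 with an estimated correlation). There the same omissions left 0 and 4 members past the test.

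Oligodendrocyte genes were lower, though the median of the progenitor list was only -0.15 without knockout replicate 2. Of 11 genes of progenitors, Gpr17 fell by 0.80 ± 0.09 and Olig2 by 0.69 ± 0.12, 2 in all, and 4 fell adjusted over the list alone. Olig1 and Enpp6 differed by -0.38 ± 0.07 and -0.38 ± 0.10, and the median was -0.29 (camera adjusted p = 0.000208; adjusted p = 0.0982 with an estimated correlation). Of 16 genes of myelinating cells 1 fell, Ugt8a, which makes myelin galactolipid, by 0.60 ± 0.08, and 6 fell adjusted over the list alone. Gsn, Mag and Mog differed by -0.50 ± 0.11, -0.36 ± 0.09 and -0.31 ± 0.08, and the median was -0.22 (camera adjusted p = 1.37e-05; adjusted p = 0.291 with an estimated correlation).

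General neuron genes were lower, with 2 of 15 past the test and 3 adjusted over the list alone. The neurofilament genes Nefh and Nefm fell by 0.60 ± 0.08 and 0.47 ± 0.07, and Tubb3 and Snap25 differed by -0.44 ± 0.11 and -0.19 ± 0.07. The median was -0.18 (camera adjusted p = 4.34e-05; adjusted p = 0.172 with an estimated correlation). Genes of cortical excitatory neurons were not called as a list (camera adjusted p = 0.0861), but were called as lower without knockout replicate 3 (camera adjusted p = 0.0358). Among them Neurod6 fell by 0.66 ± 0.11 as 1 of 15, and 3 fell adjusted over the list alone, with Nrgn, Tbr1 and Rorb at -0.35 ± 0.08, -0.51 ± 0.12 and -0.37 ± 0.13. Interneuron genes were not called (camera adjusted p = 0.863): Tac2 rose by 0.53 ± 0.08 as 1 of 14, and adjusted over the list alone 2 rose and 4 fell, with Pvalb, Sst and Npy at -0.45 ± 0.09, -0.30 ± 0.07 and -0.39 ± 0.10.

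Markers of neighbouring tissue differed between arrays. The choroid plexus list was lower, with a median of -0.28 (camera adjusted p = 0.00712; adjusted p = 0.483 with an estimated correlation), but 0 of 13 members passed, also adjusted over the list alone. Its mean deviation was 0.61 in wild type replicate 2, -0.38 and -0.23 in wild type replicates 1 and 3, and -0.48 to -0.41 in the knockout, and without wild type replicate 2 the list was not called (camera adjusted p = 0.0646). Ttr, the transthyretin gene, differed by -2.56 ± 1.02 and Calml4 by -0.89 ± 0.34. They differed by -1.12 and -0.46 without wild type replicate 2, and Ttr alone of the 13 then passed (adjusted p = 0.0399). The meninges and fibroblast list was higher, with a median of 0.41 (camera adjusted p = 0.000524; adjusted p = 0.438 with an estimated correlation), and 0 of 14 members passed, 2 being higher adjusted over the list alone. Its mean deviation was 0.41 and 0.74 in knockout replicates 1 and 3, 0.07 in knockout replicate 2 and -0.07 to 0.13 in wild type, with Mgp at 0.95 ± 0.23 and Ptgds at 0.33 ± 0.09. Leaving out knockout replicate 2 raised the count from 0 to 8 (median 0.56, camera adjusted p = 3.28e-06), and leaving out knockout replicate 3 lowered the median to 0.26.

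The red blood cell list was lower, with Alas2, which starts heme synthesis in erythroid cells, down by 0.87 ± 0.16 as 1 of 6 members, and 3 fell adjusted over the list alone. Slc4a1, Hbb-b2 and Bpgm differed by -0.37 ± 0.12, -0.27 ± 0.09 and -0.16 ± 0.11, and the median was -0.21 (camera adjusted p = 0.00584; adjusted p = 0.138 with an estimated correlation). Lists of the striatum, thalamus, hippocampus and endothelium were not called (camera adjusted p = 0.978, 0.221, 0.705 and 0.176). Without knockout replicate 2 the endothelial list was called as higher (camera adjusted p = 0.0291), with 4 members higher and 1 lower. Among hippocampal genes Lct fell by 0.82 ± 0.10 as 1 of 10, 3 being higher and 4 lower adjusted over the list alone, with Tdo2, C1ql2 and Wfs1 at 0.38 ± 0.08, 0.89 ± 0.24 and 0.48 ± 0.14. Among striatal genes Syndig1l rose by 0.46 ± 0.08 as 1 of 13, 2 being higher and 2 lower adjusted over the list alone, with Rarb, Gpr6 and Penk at -0.53 ± 0.13, 0.53 ± 0.15 and -0.46 ± 0.15. In the thalamus list 0 of 10 passed, also adjusted over the list alone, with Prkcd and Ramp3 at 0.22 ± 0.07 and 0.24 ± 0.08, and in the endothelial list 0 of 15, with 1 lower adjusted over the list alone and Slco1c1 and Abcb1a at -0.61 ± 0.13 and 0.39 ± 0.12.

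The heat shock, hypoxia and glycolysis, mitochondrial chaperone, general neuron, oligodendrocyte progenitor, myelinating cell and red blood cell lists had 0 members past the test without wild type replicate 2. Without knockout replicate 2 they had 2, 2, 4, 2, 4, 1 and 2. The cortical excitatory neuron, interneuron, striatal and hippocampal lists likewise went from 1 member to 0 without wild type replicate 2. Without knockout replicate 2 they had 2 lower, 1 higher and 2 lower, 2 higher, and 2 higher and 3 lower. The antioxidant, glucocorticoid and thalamus lists went from 0 members to 1 higher without that array.

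**Figure D2:**
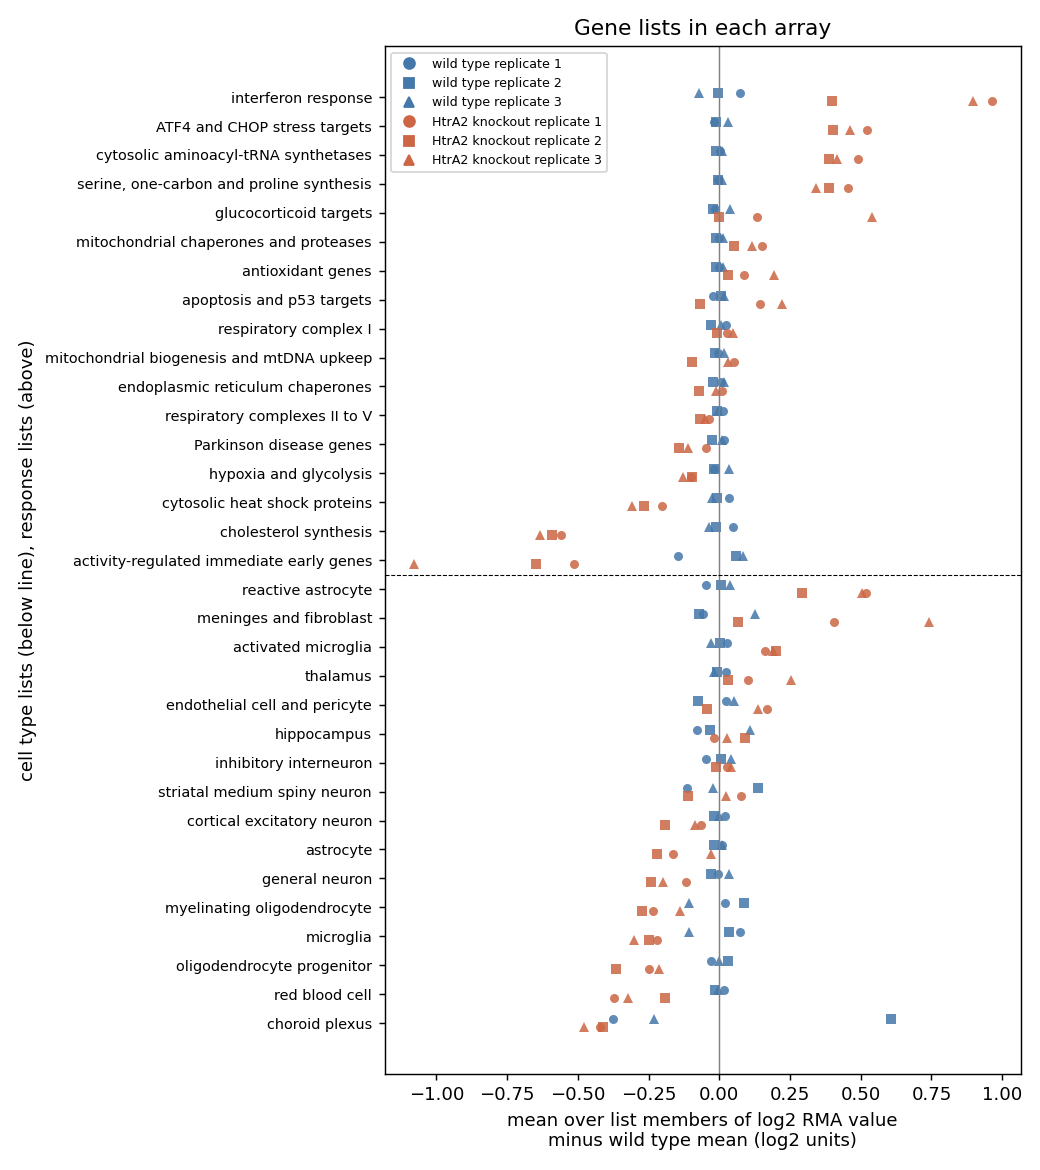
Each point is 1 array's mean, over the measured members of a gene list, of the log2 RMA value minus the wild type mean (horizontal axis, log2 units), with the lists on the vertical axis, response lists above the dashed line and cell type lists below. Colours mark the genotype and shapes the replicate. In the cholesterol list the knockout arrays lie between -0.63 and -0.56, and wild type replicate 2 stands at 0.61 in the choroid plexus list.

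Sex-linked transcripts split the arrays by animal and not by genotype. Xist, which silences an X chromosome in females, was at 10.9 in wild type replicate 1 and 11.0 in knockout replicate 3 and between 6.16 and 7.0 in the other arrays, and the Y-linked mean was 3.89 and 3.93 in those 2 arrays and 5.90 to 6.00 in the rest. Each group thus held 1 array of female and 2 of male pattern, and the Y-linked genes did not differ between genotypes (Eif2s3y at 0.35 ± 1.66, Uty at -0.28 ± 0.62). The 4 measured sex-linked genes all failed the test, also adjusted over the list alone.

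Genes beside Htra2 on its chromosome were examined because a targeted locus can carry a flanking segment of another strain. Of 175 measured genes among the 200 on each side, 5 changed (2.86%), against 595 of 18017 others (3.30%), an odds ratio of 0.861 with a 95% confidence interval of 0.275 to 2.06 (Fisher's exact test, two-sided, p = 1). They were Mthfd2, a mitochondrial one-carbon enzyme that rose by 1.43 ± 0.16 and 0.95 ± 0.16 at its 2 probe sets, Retsat (0.80 ± 0.10), Kcmf1 (0.41 ± 0.07), Egr4 (-0.64 ± 0.12) and Mrpl35 (-0.51 ± 0.10).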

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

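Leaving out both replicates numbered 2 was chosen after the values were seen; the other alternatives were planned. The 796 changed probe sets became 1757 when only probe sets above the median level were tested, 1770 with limma-trend and robust moderation, 4205 with array weights and 441 with the Y-linked level as a covariate. They became 79 at an adjusted p under 0.01, 2035 under 0.1 and 380 with a change of at least 1.5-fold. Leaving out 1 array gave 65 to 3037: 70, 65 and 107 without wild type replicates 1, 2 and 3, and 377, 3037 and 103 without knockout replicates 1, 2 and 3. Without both replicates numbered 2 the count was 314. The cause was not tested, beyond fewer tests under the filter and fewer samples without an array. Of the 796 probe sets, all those tested (708 under the filter) kept their direction in each of these fits. Outside the fit with the Y-linked covariate this was fixed in advance, since the groups did not overlap at any of the 796. Of them 796 were called without knockout replicate 2 and 63 without wild type replicate 2. Of the calls 50% were higher in the knockout, against 66.2% without knockout replicate 2, 36.6% without knockout replicate 1, 64.3% and 61.5% without wild type replicates 1 and 2, and 78.0% without both replicates numbered 2; further quantile normalization and median centring gave 54.7% and 50.8%. Both Htra2 probe sets kept their call in every fit, between -2.49 and -2.16 and between 1.07 and 1.15 when 1 array was left out. The gene lists called numbered 19 to 24 when 1 array was left out, 0 with an estimated correlation, 18 with fry in 1 direction and 29 with fry in either direction.

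The replicate numbers showed no pairing of the samples by correlation: the deviations from the group means of same-numbered arrays correlated at -0.20, -0.04 and -0.17. Deviations within a group sum to 0, so these few values cannot exclude a pairing. With the replicate block 154 probe sets were called, and 144 of the 796 were among them. No array correlated best with its own number in the other group. Of the 72 named probe sets past the test, 34 lost their call with the block: 23 of the 24 that kept it only without knockout replicate 2 (not Xaf1), and Hspa9, Hspa1b, Nefh, Neurod6, Lct, S100b, Olig2, Itgam, H2-D1, Retsat and 1 of the Mthfd2 probe sets. The Y-linked covariate ended 16 calls.

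Leaving out 1 array moved some other values by over 1.5 times without a change of sign. Without knockout replicate 3 the medians of the general neuron, glucocorticoid and antioxidant lists were -0.12, 0.11 and 0.05, that of the apoptosis list 0.004, and Fkbp5, Zbtb16 and Ccl3 differed by 0.38, 0.19 and 0.32. Without knockout replicate 2 Hsp90b1, Rorb and Bpgm differed by -0.15, -0.23 and -0.04, and without wild type replicate 2 Penk differed by -0.28. The median of the Parkinson list was -0.11 without knockout replicate 1.

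Some results near 0 changed sign, none of them called. The odds ratio near Htra2 was 1.43 with 100 genes on each side (Fisher's exact test, p = 0.371) and 0.637 with 50. Uty went to 0.00579 without wild type replicate 2 and 0.41 without knockout replicate 3, and ranged from -0.82 to 0.41. Eif2s3y went to -0.47 with array weights, -1.32 without wild type replicate 1, -0.61 and -0.34 without knockout replicates 1 and 2, and ranged to 2.01. By list medians, camera's direction turned for the striatal list at 0.00712 with the filter, 0.0181 with limma-trend and with the replicate block, 0.0248 with median centring and -0.0039 with the mean of a gene's probe sets. Without 1 array it turned at -0.0222 and 0.0166 without wild type replicates 1 and 3 and at 0.0285 and -0.0375 without knockout replicates 1 and 3, in a range of -0.0375 to 0.0914. The interneuron list turned at 0.0745 with array weights, 0.0321 with fry, 0.0759 without both replicates numbered 2, 0.0731 without wild type replicate 3 and 0.0797 without knockout replicate 2, in a range of -0.00826 to 0.0797. The complex I list turned at 0.0184 without wild type replicate 2 and 0.0157 without knockout replicate 3, in a range of 0.0157 to 0.0361. The mitochondrial biogenesis list turned at 0.0563 without wild type replicate 2 and at 0.0318 and 0.0284 without knockout replicates 1 and 3, in a range of 0.0284 to 0.0927. The cause was not tested.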

Other observations

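Host transcripts of small nucleolar RNAs, which no list held, were among the most clearly raised. Snhg1 rose by 1.38 ± 0.10, Snhg12 by 1.33 ± 0.08, Gas5 by 1.11 ± 0.08 and Snhg16 by 1.07 ± 0.10, and these 4 were chosen after their values were seen. The tests of other host transcripts, of ribosomal protein genes, of clock genes, of fewer meningeal cells and of a share of wild type RNA were stated before their results were seen; the remaining tests here were chosen after. Over the other 13 measured host transcripts the median was 0.32, 11 were higher, and Snhg5, Zfas1, Snhg8 and Snhg10 rose by 1.10 ± 0.13, 0.63 ± 0.08, 0.62 ± 0.08 and 0.48 ± 0.08. Camera gave them p = 0.000205, and p = 0.144 with an estimated correlation, so a rise of host transcripts as a class was called only in the preset form of the test. Ribosomal protein genes, which share a start sequence with many host transcripts, had a median of 0.21 over 49 genes, 45 of them higher and 2 past the test. Camera with the preset correlation gave them p = 1.64e-12. Their median lies between what a rise of all such transcripts would need and what would exclude it.

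Dbp, an output gene of the circadian clock, rose by 0.98 ± 0.08. Of 10 other clock genes 7 moved in the direction of Dbp's phase, and Ciart, Nr1d1 and Tef rose by 1.20 ± 0.15, 0.63 ± 0.07 and 0.38 ± 0.07. Per2 and Per3 differed by -0.06 ± 0.20 and -0.06 ± 0.10 and Npas2 by 0.26 ± 0.13, against that phase. Whether the tissue was taken at another time of day cannot be told apart from an effect of genotype, since 7 lies between the bounds set beforehand and no time of dissection is given.

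Knockout replicate 2 lay apart from the other knockout arrays: 2864 probe sets were over 0.5 log2 units from their mean, against 594 and 761 for replicates 1 and 3. Degraded RNA in this array is argued against, since 0 of 4 control transcripts had a 3' to 5' difference outside the range of the other arrays. Wild type replicates 1 and 2 had the lowest differences at all 4. For pyruvate carboxylase they were 1.55 and 1.54, against 1.93 in wild type replicate 3 and 1.67 to 2.19 in the knockout. An effect of RNA quality on the comparison of genotypes was not tested. Less meningeal tissue as the whole cause of the distance of knockout replicate 2 is argued against too. Of its 2864 probe sets 55.5% were lower, short of the share that had been required beforehand. The array did differ by brightness, with median differences of 0.08, 0.14, 0.06, -0.09 and -0.07 over 5 equal bins of probe sets from dim to bright, but as the whole cause this is argued against, since 2434 remained after further quantile normalization and 2328 after the trend was removed, against at most 749 and 785 in the other knockout arrays. A share of wild type RNA met the bound stated for it. The median position of this array between wild type (0) and knockout (1) was 0.497, over 158 probe sets changed over 2-fold without it. That is below the 0.878 that the falling Htra2 probe set gives. These probe sets were picked by the other knockout arrays, which by itself pulls a left-out array towards wild type. Replicates 1 and 3 left out in the same way stood at 0.937 and 1.05, over only 78 and 41 probe sets. Their reference held replicate 2, which raises their positions. A mix as the whole cause is argued against, though not excluded, by a comparison chosen later. The position of 0.497 needs a share of 50.3%, which would put the falling Htra2 probe set at 8.17, 1.09 above the 7.08 measured. The SD was at most 0.0833 in wild type and in knockout replicates 1 and 3. The share of 50.3% carries the same pull towards wild type. A share near the 12.2% that Htra2 allows stays open. So does a difference in labelling or hybridization, since 17 of 18 probe sets for hybridization spike-ins were lowest in this array. These probe sets measure only bioB, bioC, bioD and cre, so they are not independent of each other. Their median difference was -0.41 from the other knockout arrays, and spike-ins do not come from the animals. A difference between animals was not tested and stays open too.

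The choroid plexus list was lower and the meningeal list higher in the knockout, but neither was called with an estimated correlation (camera adjusted p = 0.483 and 0.438). Choroid plexus tissue carried into wild type replicate 2 may account for much of the first, since without that array the median went from -0.28 to -0.0748 (camera adjusted p = 0.0646). Without that array Ttr still differed by -1.12 (adjusted p = 0.0399), in every knockout array below the other wild type arrays. Ttr alone of the 13 members passed, and this comparison was chosen later, so carried tissue as the whole cause is not excluded. Meningeal tissue carried into knockout replicates 1 and 3 may account for the second, since replicate 2 stood at 0.0672, within the wild type range of -0.07 to 0.13. A change of these tissues by genotype stays open as well.

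The Htra2 probe sets moved in opposite directions. Mixed-up samples are argued against, since the falling probe set changed by -2.27 with every knockout array below every wild type array. A rise of the overlapping neighbours Aup1 and Loxl3 is argued against too, since their own probe sets had upper 95% confidence limits of 0.187 and 0.0393. RNA from a part of the gene that the deletion left in place could give the rise of 1.11, but the positions of the probes relative to the deletion are not given in the sources used here, so this cannot be told apart from other origins.

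The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10, gave as many changed probe sets or as many called lists. The real split gave 796 changed probe sets and the highest of the others 0. For gene lists it gave 20, and the others up to 14. Every other split mixes the genotypes unevenly, so part of the genotype difference remains between its groups and part enters their spread. Neither the 0 nor the 14 is therefore a level free of genotype, and these splits do not test the preset correlation.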
